A study of Mus musculus with 94 samples.

How the data were processed

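Of the 94 samples of the series, 18 were analysed here: 14 poly(A) RNA-seq libraries and 4 PRO-seq libraries of mouse embryonic stem cells carrying an FKBP degron on RAD21 or WAPL. The ChIP-seq, calibrated ChIP-seq, Hi-C and CHART libraries were not analysed here. Groups, clones and replicate numbers came from the sample titles and descriptions. Per the labels' protocols, stem cells were kept on irradiated embryonic fibroblasts, differentiated as embryoid bodies, and harvested at day 7 or 10, with dTAG-13 at 500 nM or the same volume of DMSO.

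The 3 RNA tables hold raw counts per gene as deposited by the authors, not normalized, with whole numbers whose totals differ between libraries. The PRO-seq table holds expected counts as deposited by the authors, in multiples of 0.5, which were rounded to whole numbers before testing. Per the submitters' processing notes the tools TopHat2, Novoalign, Bowtie2, HOMER, DESeq and DESeq2 and the genome builds mm9, hg19 and dm6 were used, without a role or version for each. The counting rule, its use of strand and the treatment of reads from multi-copy genes are not given in the sources used here. Tables held 24421 genes (WAPL days 4 to 7), 14997 (WAPL days 7 to 10), 15363 (RAD21 RNA) and 22529 (RAD21 PRO-seq). The middle pair may have gone through a gene filter, but no header states one. Chromosomes and symbols came from the files' gene labels. The RefSeq gene table given with the data is of another build, GRCm38.p6, and served for names and the order of neighbouring genes only. No reference genome was used, and the files held no counts per allele, so allele shares were not computed.

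Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05). The clone was a term for WAPL days 4 to 7 and for both RAD21 comparisons. Residual degrees of freedom were 3 for WAPL days 4 to 7, 2 for days 7 to 10, 1 for each RAD21 comparison and 5 for the test of the difference between windows. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 over lists with at least 5 tested members, and X-linked genes without Xist and Tsix against all other tested genes. Estimated correlations and fry served as alternatives. CPM are counts scaled by the library's total and TMM factor, given as mean ± SD. Figures were drawn with matplotlib 3.10.9.

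The tests, gene lists, main designs and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 8 largest rises and 8 largest falls past the threshold with an average log2 CPM of at least 2 and the same sign in every pair, leaving out predicted genes, RIKEN clones, pseudogenes and small RNA entries of the Mir, Snora, Snord and Scarna families. It adds up to 4 members of each list by smallest p, and Rad21, Wapl, Ctcf, Nipbl, Xist, Tsix, Jpx, Rlim, Pou5f1, Ezh2 and Myc in every case. A few genes the rule names are not reported here. The lists covered the cohesin machinery, Polycomb components, Hox genes, other Polycomb target regulators, pluripotency, primed epiblast, neural, mesoderm, endoderm, trophoblast, fibroblast and feeder, endothelial and blood markers, the X-inactivation centre, escape genes, imprinted genes, clustered protocadherins, germline genes, 2-cell-like genes, p53 targets, mitosis, DNA replication, immediate early genes, the integrated stress response, interferon response, ribosomal proteins and replication-dependent histones.

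Replicates of a group differed beyond sampling noise, with a chi-square per gene between 12.9 and 55.3, so none were counted as 1 sample. Deviations of same-numbered libraries from their group means correlated with r = 0.52, 0.54 and 0.63 in the 3 pairs of WAPL days 4 to 7. The last pair is clone H2 and the clone was not taken out, so 0.63 does not separate clone from number. Within clone H7 differently numbered libraries gave r = 0.11 and 0.02, so the numbers may pair its samples. The main fit held the clone but no replicate block, and the fit with that block called 3993 genes. Same-clone libraries of the RAD21 sets correlated with r = 0.68 (RNA) and 0.72 (PRO-seq), where the clone term pairs them.

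Alternatives were RLE scaling and library totals, no filter and a mean count of at least 50, DESeq2 1.42.0, limma-voom, other designs, leaving out each library, and, chosen after seeing the data, other quasi-likelihood settings, a clone-by-treatment term, and leave-one-out fits of X-linked genes, gene lists and the difference between windows. Each count test was tested on simulated data with 200 changed genes drawn from the real means and library sizes. The simulation was changed after its first result was seen, from dispersions without the treatment term to dispersions with it. With edgeR the share of false genes among calls in the first and second version was 11% and 12.9% for WAPL days 4 to 7, 14.6% and 7% for days 7 to 10, 16.3% and 5.2% for RAD21 RNA, 28% and 6.7% for PRO-seq, and 1.8% and 9.4% for the difference between windows, mostly above the nominal 5%. Planted 2-fold changes were recovered in 38.8% and 88.1%, 23.9% and 13.4%, 76.1% and 97%, 68.2% and 89.6%, and 13.6% and 17.9% of genes in the same order. DESeq2 gave false shares of 32.1% and 17.9%, 22.8% and 29.1%, 10.1% and 1.2%, and 13.5% and 0% in the 4 comparisons.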

Results

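The data were poly(A) RNA-seq and PRO-seq counts per gene from female mouse embryonic stem cells, a CAST/Ei x 129 hybrid, in which RAD21 or WAPL carried an FKBP degron. RAD21 is a core subunit of cohesin, the ring complex that extrudes chromatin loops, and WAPL is the factor that releases cohesin from chromatin. The small molecule dTAG-13 at 500 nM directs the tagged protein to degradation, and DMSO was the vehicle. Cells were differentiated as embryoid bodies. The WAPL lines were treated on days 4 to 7 (clone H7 replicates 1 and 2, and clone H2, with 3 DMSO and 3 dTAG-13 libraries) or on days 7 to 10 (clone H7, 2 and 2). The RAD21 clones C4 and G9 were treated for 8 h, with RNA taken at day 10 and nascent RNA, mapped by PRO-seq at engaged RNA polymerases, at day 7 (1 library per clone and treatment). The title of the series names Polycomb-mediated repression and X inactivation as the processes of interest.

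Total counts per library ranged from 8413212 to 35388461 in the WAPL day 4 to 7 set, from 12076585 to 26956675 in the day 7 to 10 set, from 13802076 to 33808921 in the RAD21 RNA set and from 14269544.5 to 34335988.5 in the PRO-seq set. The shallowest library was DMSO clone H2 on days 4 to 7. Floors cover counting error only. A floor of 3 counts corresponded to between 0.0848 and 0.357 CPM over the 18 libraries. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named, and fold changes are log2 of dTAG-13 over DMSO with their SE. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples.

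The degron acts on protein, so the tagged transcript does not check the labels. Wapl stood at 615 ± 324 CPM (SD, n = 3) with DMSO and 636 ± 362 CPM with dTAG-13 on days 4 to 7 (log2 0.02, SE 0.11, adjusted p = 0.939). Its large SD came from the clones, with 759 and 842 CPM in the DMSO libraries of clone H7 and 244 CPM in clone H2. Rad21 stood at 226 ± 34.9 and 250 ± 47.9 CPM in the RAD21 RNA set (n = 2 each, log2 0.14, adjusted p = 0.118) and at 168 ± 0.144 and 187 ± 6.02 CPM in PRO-seq (log2 0.16, adjusted p = 0.152).

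The first comparison asked which transcripts differed after 3 days with dTAG-13 in the WAPL lines, on days 4 to 7. Genes of the 2-cell-like state rose most: Zscan4d went from 3.7 ± 2.84 to 37.3 ± 33.6 CPM (SD, n = 3 each, log2 3.17, SE 0.24, adjusted p = 7.38e-04), Zscan4c rose by 3.45, and the deubiquitinase genes Usp17lb and Usp17la rose by 4.53 and 4.17. Of 12 measured members of this list 11 rose and none fell, with a list median of 3.18. The treated libraries spread widely, with an SD close to the mean. Most of these genes are multi-copy, so the division of reads among Usp17l and among Zscan4 copies is uncertain. Aldh1a1, a retinaldehyde dehydrogenase, rose from 0.633 ± 0.1 to 7.45 ± 1.41 CPM. In the set test (camera, preset correlation 0.01) the list stood above other genes with adjusted p = 1.59e-38, and with adjusted p = 0.0832 with an estimated correlation. No list call in any of the 4 comparisons held with an estimated correlation. That version had little power with 1 to 3 residual degrees of freedom per comparison. A failure there, here and below, therefore leaves a list undecided and is not evidence that it did not move.

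**Figure D1:**
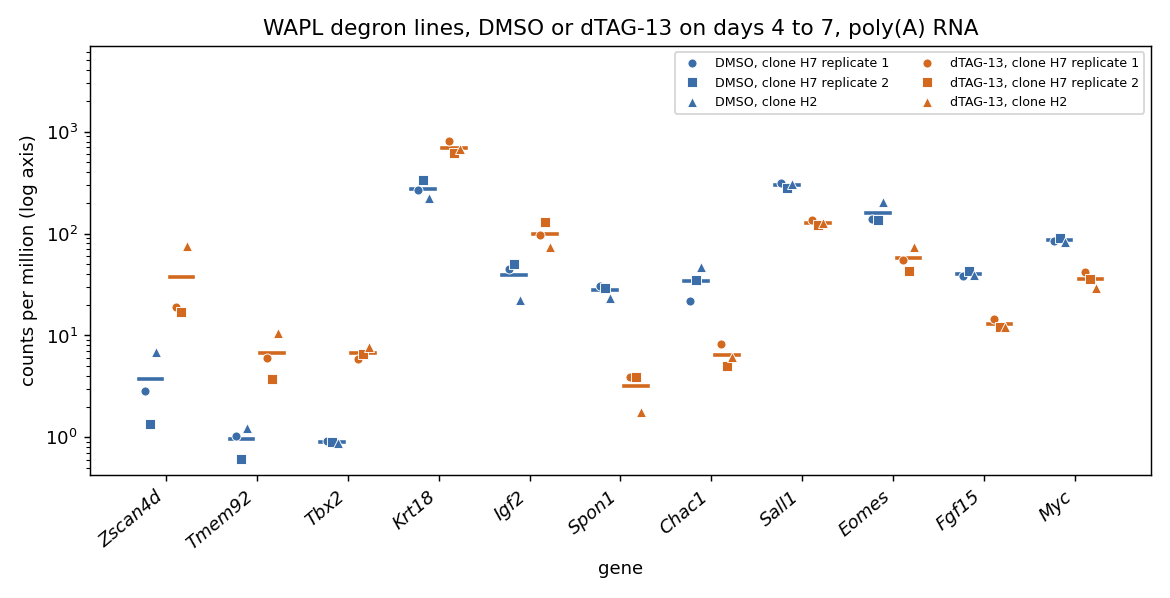
CPM (log axis) of 11 genes in the 6 poly(A) RNA libraries of the WAPL degron lines on days 4 to 7; blue points are DMSO, orange points dTAG-13, marker shape gives the clone and replicate, and bars are means of 3 libraries. Zscan4d went from a mean of 3.7 to 37.3 CPM and Spon1 from 27.7 to 3.21 CPM.

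Among Hox genes and other regulators repressed by Polycomb in stem cells, most calls were rises. Of 15 measured Hox genes 12 rose and none fell (13 when adjusted over the list alone), among them Hoxb1 (log2 2.84, SE 0.34, adjusted p = 0.00297), Hoxa4 (2.87) and Hoxc13 (2.33). Hoxa4 stood at 0.138 CPM with DMSO, where floors of 3 counts ran from 0.0848 to 0.357 CPM, so its fold change is uncertain. The list adjusted p was 2.67e-16, and the adjusted p = 0.0775 with an estimated correlation. Of 48 measured Polycomb target regulators outside the Hox clusters 13 rose and 4 fell (24 and 5 adjusted over the list alone). Tbx2 rose by 2.85 and Barx1 by 2.12, while the growth factor gene Fgf8 fell by 1.36 and Sall1 fell by 1.22, from 299 ± 19.7 to 128 ± 6.18 CPM. The list adjusted p was 1.15e-04, and the adjusted p = 0.235 with an estimated correlation. Of 30 genes for Polycomb components themselves 1 rose (Cbx8, 1.56) and 3 fell (Cbx2 at -0.70, Pcgf2 at -0.46 and Cbx7 at -0.40), and the list did not pass (adjusted p = 0.328). Cbx8 stood at 0.257 CPM with DMSO, also within the range of those floors. Ezh2, the catalytic subunit of Polycomb complex PRC2, had a log2 fold change of -0.07 (adjusted p = 0.647).

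Genes of the early embryo went in different directions. Of 10 primed epiblast genes 7 fell, including Fgf15 (from 40.1 ± 2.55 to 12.9 ± 1.29 CPM), the DNA methyltransferase gene Dnmt3b (-0.93) and Fgf5 (-0.92). The list adjusted p was 6.09e-09, and the adjusted p = 0.0832 with an estimated correlation. Of 27 pluripotency genes 3 fell (Sox2, L1td1 and Sall4) and the list did not pass (adjusted p = 0.215, or 0.0145 without dTAG-13 replicate 1). Of 20 mesoderm and cardiac muscle genes 7 rose and 2 fell: Hand1 rose by 1.28 and the troponin gene Tnnc1 by 1.37, while Eomes, an early mesendoderm regulator, fell by 1.48 (list adjusted p = 0.0362, and adjusted p = 0.409 with an estimated correlation). That list did not pass without dTAG-13 replicate 1 (0.135) or DMSO replicate 2 (0.0731). Of 21 endoderm genes 5 rose and 3 fell, and the list did not pass (adjusted p = 0.328). Col4a2 rose by 0.70 and Foxa2 fell by 2.03, although Foxa2 varied between libraries (11.2 ± 12 CPM with DMSO). Of 13 trophoblast genes 8 rose and 1 fell, with Krt18 going from 277 ± 57 to 699 ± 97.4 CPM and Krt7 from 9.66 ± 3.86 to 29.7 ± 4.66 CPM (list adjusted p = 3.46e-06, and adjusted p = 0.0958 with an estimated correlation). Of 19 fibroblast and feeder genes 9 rose and 1 fell, among them Acta2 (2.38), Col6a1 (1.23) and Col1a2 (0.93); stem cells were grown on embryonic fibroblast feeders before differentiation, and the counts do not separate feeder RNA from that of the embryoid bodies (list adjusted p = 5.73e-06, and adjusted p = 0.235 with an estimated correlation).

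Stress and immune gene groups also moved. Of 23 integrated stress response genes 13 fell and none rose: Chac1, a glutathione-degrading enzyme, went from 34.4 ± 12.2 to 6.45 ± 1.62 CPM, and the amino acid transporter gene Slc7a5 fell by 1.20 (list adjusted p = 4.06e-11, and adjusted p = 0.322 with an estimated correlation). Of 23 interferon response genes 12 rose, including Cxcl10 (1.40) and Isg15 (1.46), with list adjusted p = 2.07e-07 and adjusted p = 0.296 with an estimated correlation. Of 25 p53 targets 11 rose, including Btg2 (0.77) and Perp (0.95), with list adjusted p = 6.92e-07 and adjusted p = 0.235 with an estimated correlation. Of 30 DNA replication genes 8 fell, including Rrm2 (-0.68) and Mcm10 (-0.43), with list adjusted p = 1.23e-06 and adjusted p = 0.372 with an estimated correlation. Myc, a growth-promoting transcription factor, fell by 1.28, from 85.9 ± 4.77 to 35.7 ± 6.22 CPM. Other large falls were Spon1 (-3.12), the haemato-endothelial regulator Etv2 (-2.16), Jph4 (-2.15) and Pck2 (-2.15).

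Of 38 measured clustered protocadherin genes 23 rose and none fell, by about 0.5 each among the gamma members (Pcdhgc5 0.53, Pcdhga1 0.53). Gamma members share their 3' exons and had nearly equal CPM, so they do not count as separate genes (list adjusted p = 1.59e-10, and adjusted p = 0.235 with an estimated correlation). Of 35 imprinted genes 8 rose and 2 fell: Igf2 rose from 39.2 ± 15.1 to 99.7 ± 27.9 CPM, Grb10 rose by 0.94 and Magel2 fell by 1.10 (list adjusted p = 0.0125, and adjusted p = 0.235 with an estimated correlation). Poly(A) libraries measure only transcripts with a poly(A) tail, so histone transcripts without one were not measured. Of 22 replication-dependent histone genes 4 rose, led by Hist1h2bc (2.26). That list passed without a replicate block (adjusted p = 0.0441, and adjusted p = 0.409 with an estimated correlation) and did not pass with one (adjusted p = 0.0591), nor without dTAG-13 replicate 1 (0.596) or the DMSO or dTAG-13 library of clone H2 (0.141 and 0.227).

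The remaining lists were as follows. Of 20 neural genes 2 rose, including Neurod1 (1.15), and 5 fell, including Nes (-0.77) and Sox3 (-0.75), and the list did not pass (adjusted p = 0.25). Of 25 germline genes 4 rose and 1 fell, with Tdrd7 up by 0.72 and Sycp2 by 1.35 (list adjusted p = 0.00173, and adjusted p = 0.36 with an estimated correlation). Of 23 immediate early genes 7 rose, including Ier3 (1.02) and Ctgf (0.70), and Myc fell (list adjusted p = 0.00326, and adjusted p = 0.409 with an estimated correlation). Of 26 mitosis genes Bub1b fell by 0.37 (list adjusted p = 0.0105, and adjusted p = 0.467 with an estimated correlation). None of 18 genes of the cohesin machinery passed, with a median of -0.17 (list adjusted p = 0.0309, and adjusted p = 0.409 with an estimated correlation). Of 85 ribosomal protein genes, which have many processed copies, Rpl10l rose by 1.04 and 3 fell, led by Rpl36a (-1.47), with list adjusted p = 0.00296 and adjusted p = 0.639 with an estimated correlation. The cohesin list did not pass without dTAG-13 replicate 1 (0.162) or DMSO replicate 2 (0.0593), and the mitosis list without the DMSO or dTAG-13 library of clone H2 (0.0723 and 0.0794). The ribosomal list did not pass without dTAG-13 replicate 2 (0.332) or the same clone H2 libraries (0.0555 and 0.0632). Also short of the threshold were the lists for blood (2 of 7 fell, Tal1 by 1.73 and Epor by 0.67, adjusted p = 0.0623), endothelium (of 11, Eng rose by 0.50 and Sox18 fell by 1.38, adjusted p = 0.781), the X-inactivation centre (2 of 10 fell, Tsx by 1.76 and Ftx, adjusted p = 0.297) and genes that escape X inactivation (of 17, 3 rose, including Bgn by 1.08, and 1 fell, adjusted p = 0.847). The blood list passed without dTAG-13 replicate 1 (0.0145), DMSO replicate 2 (0.0316), or the DMSO or dTAG-13 library of clone H2 (0.00108 and 0.00106).

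In total 1376 genes rose and 833 fell of 14544 tested, 602 and 165 of them by at least 2-fold. Of the 2209, 2208 moved the same way in every pair, but they were called from these same pairs, so this is no separate check. Among all tested genes the share was 59.4%. With the replicate number as a block 2234 rose and 1759 fell, without the clone term 658 and 336, and in the clone H7 libraries alone 270 and 90. The count was 967 without DMSO replicate 1, 977 without DMSO replicate 2, 4433 without dTAG-13 replicate 1, and 341 or 342 without the DMSO or dTAG-13 library of clone H2.

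The second comparison moved the window to days 7 to 10 in clone H7. No gene passed with edgeR (0 of 14110 tested), 926 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 25 higher and 15 lower. None of these fits used the replicate number as a block. With that block edgeR called 5141 genes. Deviations of same-numbered libraries from their group means correlated with r = 0.79, so the numbers may pair the samples. With 2 libraries per group this is 1 value for both pairs, and in the labels the pairs share only a number. The count of 0 depends on the design and does not show that nothing changed. The smallest p-values belonged to Lingo1 (5.79 ± 0.678 and 21.8 ± 3.3 CPM, n = 2 each, log2 1.91), Esm1 (2.88) and Gm5662 (2.87) with higher counts, and to Myb (-1.84), Sall1 (-0.96) and the Hedgehog target Gli1 (-1.60) with lower counts, each with adjusted p = 0.663. Adjusted over the list alone, 15 of 22 Hox genes and 9 of 10 2-cell-like genes were higher. Their list medians were 1.29 and 2.05, with list adjusted p-values of 4.08e-23 and 2.46e-19, and the adjusted p = 0.422 for each with an estimated correlation. Myc had a log2 fold change of -0.62 (adjusted p = 0.69). Of the 27 lists 15 passed camera, among them pluripotency (median -0.34) and interferon response (median 0.39), and none passed with an estimated correlation (smallest adjusted p = 0.422). In 2 versions of data simulated for this comparison 89.2% and 86.4% of planted 4-fold changes and 23.9% and 13.4% of planted 2-fold changes were recovered. Without DMSO replicate 1, DMSO replicate 2, dTAG-13 replicate 1 or dTAG-13 replicate 2 the counts were 31, 143, 53 and 27, with the lone library assumed to vary like the other group.

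A test of the difference between the 2 windows in one fit of the 10 WAPL libraries found no gene whose response differed (0 of 14326 with edgeR, 423 at an unadjusted p under 0.05), while the fit with the replicate number as a block called 5, 2 higher and 3 lower. Across 13897 genes the responses in the separate fits correlated with Pearson r = 0.77 and Spearman rho = 0.74, where genes are not independent replicates. Of 2126 genes called on days 4 to 7 and tested in both, 2076 (97.6%) had the same sign on days 7 to 10. The median difference in response, days 7 to 10 minus days 4 to 7, was -0.86 for Hox genes and -1.05 for 2-cell-like genes, with no member past the threshold. Only days 4 to 7 include clone H2, so these differences mix window and clone. On days 4 to 7 the 2-cell-like pair medians were 2.62 and 3.13 in clone H7 and 3.85 in clone H2. In the clone H7 libraries alone the test of the difference also called 0 genes. In both simulated versions of this test 69.7% of planted 4-fold differences were recovered, and 13.6% and 17.9% of 2-fold ones.

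The third comparison asked which transcripts differed after 8 h of dTAG-13 in the RAD21 lines at day 10. Magel2, an imprinted gene of the Prader-Willi region, fell from 65.6 ± 6.94 to 6.32 ± 0.0563 CPM (n = 2 each, log2 -3.39, SE 0.09). Foxc2, a forkhead transcription factor, fell by 3.99 and the metalloprotease gene Adamts15 fell by 3.94, and Cemip (-2.47), Chst1 (-2.36), Cbln1 (-2.23) and Gjb2 (-2.15) also fell. Rises were smaller: the cytokine gene Il24 rose from 7.54 ± 1.21 to 21.6 ± 2.11 CPM (log2 1.52, SE 0.11), followed by Krt17 (1.48), Cyp1a1 (1.33), Ankrd1 (1.31), Hoxd1 (1.30) and Fosl1 (1.20).

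Of 27 pluripotency genes 16 fell and none rose, including Sox2 (from 161 ± 51 to 96.9 ± 41.6 CPM), Klf2 (-0.62), Fgf4 (-0.78), Prdm14 (-1.65) and Pou5f1 (-0.26). The list adjusted p was 6.32e-14, and the adjusted p = 0.77 with an estimated correlation. Without DMSO replicate 1 the pluripotency list did not pass, and without dTAG-13 replicate 2 its direction turned. In the RAD21 sets each fit without 1 library also drops the clone term, so clone baselines enter it. List changes without 1 library, here and below, therefore cannot be read as effects of treatment alone. Of 55 Polycomb target regulators outside the Hox clusters 8 rose and 21 fell, with Hand1 (-0.91), Wnt5a (-0.96) and Zic2 (-0.53) among those that fell (list adjusted p = 8.74e-04, and adjusted p = 0.77 with an estimated correlation, or 0.0644 without DMSO replicate 2). Of 25 Hox genes 2 rose (Hoxd1 and Hoxb3) and none fell (adjusted p = 0.22, or 7.21e-07 without DMSO replicate 1 and 1.06e-05 without dTAG-13 replicate 2). Of 40 clustered protocadherins 17 fell and none rose, including Pcdhb22 (-1.79) and Pcdha12 (-0.70), with list adjusted p = 8.46e-09 and adjusted p = 0.77 with an estimated correlation. Dll1 (-1.20) and Sox1 (-1.75), of the neural list, Cxcr4 (-1.28), of the endoderm list, and the endothelial receptor gene Kdr (-0.87) also fell.

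Of 26 mitosis genes 17 rose and none fell, by small amounts such as 0.50 for Kif23 and 0.44 for Cenpe (list adjusted p = 8.46e-09, and adjusted p = 0.77 with an estimated correlation). Of 23 immediate early genes 11 rose and 3 fell, with Atf3 going from 32.1 ± 0.989 to 63 ± 4.25 CPM and Maff rising by 0.86 (list adjusted p = 1.20e-04, and adjusted p = 0.77 with an estimated correlation). Of 25 p53 targets 10 rose, including Polk (0.31) and Mdm2 (0.31), and Plk2 fell (list adjusted p = 3.99e-04, and adjusted p = 0.77 with an estimated correlation). Of 35 imprinted genes 7 rose and 9 fell, Peg3 (-0.93) and Magel2 among the latter and Kcnq1ot1 (0.64) and Phlda2 (0.90) among the former, and the list did not pass (adjusted p = 0.349). Of 18 genes for the cohesin machinery 3 rose, Stag1 (0.33), Espl1 (0.20) and Nipbl (0.18), and 2 fell (adjusted p = 0.529, or 0.0326 without DMSO replicate 1 and 0.0332 without dTAG-13 replicate 2). Without dTAG-13 replicate 2 the immediate early and p53 lists did not pass (0.0652 and 0.251), and the imprinted list passed (0.00136).

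Further lists moved in parts. Of 10 primed epiblast genes 2 rose and 5 fell, with Pou3f1 down by 0.52 (list adjusted p = 0.0136, and adjusted p = 0.77 with an estimated correlation). Of 22 endoderm genes 2 rose and 7 fell (list adjusted p = 0.0349, and adjusted p = 0.77 with an estimated correlation), and of 30 DNA replication genes 5 fell, with Cdc6 at -0.30 (list adjusted p = 0.00428, and adjusted p = 0.77 with an estimated correlation). Of 24 germline genes 2 fell (list adjusted p = 0.0227, and adjusted p = 0.77 with an estimated correlation), and of 19 neural genes 2 rose and 5 fell (list adjusted p = 0.0476, and adjusted p = 0.77 with an estimated correlation). Without the clone term the endoderm (0.3), germline (0.101) and neural (0.111) lists did not pass camera, while the other called lists did. Of 30 genes for Polycomb components 1 rose and 5 fell, with Suz12 at -0.25 (adjusted p = 0.625), of 86 ribosomal protein genes 17 rose and 7 fell (adjusted p = 0.22), and of 24 mesoderm and cardiac muscle genes 4 rose and 7 fell (adjusted p = 0.295). None of 5 measured 2-cell-like genes passed (median -0.43, adjusted p = 0.4). Without dTAG-13 replicate 2 the primed epiblast, neural and DNA replication lists did not pass (0.115, 0.728 and 0.0693), the germline list turned (0.125), the ribosomal list turned and passed (4.95e-06) and the mesoderm list passed (0.00953). Without DMSO replicate 1 the neural and DNA replication lists did not pass (0.506 and 0.127), the germline list turned (0.471) and the mesoderm list passed (6.64e-05). Without DMSO replicate 2 the primed epiblast and DNA replication lists did not pass (0.156 and 0.0706), the endoderm list turned (0.241) and the ribosomal list passed (0.0453). Without dTAG-13 replicate 1 the endoderm list turned (0.88), and the ribosomal and 2-cell-like lists passed (3.09e-11 and 0.0438).

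In total 1422 genes rose and 1286 fell of 14470 tested, 51 and 177 by at least 2-fold. This rested on treating the clone as a term: without it 0 rose and 1 fell, DESeq2 with the clone called 221 and 254, and scaling by library totals alone gave 710 rises and 1303 falls (35.3% rises). Leaving out DMSO replicate 1 (clone C4), DMSO replicate 2 (clone G9), dTAG-13 replicate 1 or dTAG-13 replicate 2 also removes the clone term and left 94, 65, 50 and 16 genes, and with 1 residual degree of freedom the spread was pooled over genes, so the smallest p-values of single genes are not printed. Baselines of the clones then enter the fold changes.

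The fourth comparison measured engaged polymerase after 8 h of dTAG-13 in the RAD21 lines at day 7. The signal fell over Adamts15 (from 28.4 ± 19.2 to 3.48 ± 0.258 CPM, n = 2 each, log2 -2.78, SE 0.22), Tmem200a (-2.42), the retinoic acid hydroxylase gene Cyp26a1 (-2.29), the activin antagonist gene Fst (-2.17) and the mesoderm regulator T (-1.81). The clones differed in baseline for several of these, with T at 82.2 ± 89.1 CPM and Fst at 38.7 ± 41.9 CPM in DMSO. Signal also fell over Sall1 (-1.16), Zic2 (-1.27), Fgf8 (-1.05) and Magel2 (-1.66). The largest rises were at short non-coding RNA genes, Rnu73b (2.89), Rmrp (from 65.8 ± 29.2 to 365 ± 38.9 CPM, log2 2.55), Rnu12 (2.02) and Rpph1 (1.88), followed by Kctd16 (1.66), Ebf2 (1.45) and St18 (1.44).

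Of 26 pluripotency genes 11 fell and none rose, with Nanog at -0.77, Sox2 at -0.80 and Pou5f1 at -0.76 (list adjusted p = 5.35e-05, and adjusted p = 0.681 with an estimated correlation). Of 10 primed epiblast genes 4 fell, including Fgf5 (-1.12) and Dnmt3b (-0.78), with list adjusted p = 1.33e-05 and adjusted p = 0.681 with an estimated correlation. Of 22 immediate early genes 12 fell and 1 rose, including Egr1 (from 538 ± 57.8 to 359 ± 35.1 CPM), Ier2 (-0.40) and Nr4a1 (-0.40), with list adjusted p = 4.17e-05 and adjusted p = 0.681 with an estimated correlation. Of 25 p53 targets 12 rose and none fell, including Eda2r (0.58), Mdm2 (0.73) and Ckap2 (0.47), with list adjusted p = 1.13e-06 and adjusted p = 0.681 with an estimated correlation. Of 42 clustered protocadherins 6 fell, among them Pcdha7 (-0.46) and Pcdha9 (-0.43), which lie in one array with overlapping transcription units (list adjusted p = 7.16e-05, and adjusted p = 0.681 with an estimated correlation). Of 28 imprinted genes 9 rose, including Cdkn1c (1.26) and Sgce (0.78), and 3 fell, including Peg3 (-0.86), and the list did not pass (adjusted p = 0.13). Of 62 ribosomal protein genes 1 rose (Rpl7a, 0.71) and 3 fell (list adjusted p = 0.00115, and adjusted p = 0.681 with an estimated correlation), and of 20 mesoderm and cardiac muscle genes 3 fell, T, Eomes and Tcf15 (list adjusted p = 0.0204, and adjusted p = 0.681 with an estimated correlation). Without the clone term the mesoderm list did not pass camera (0.233), while the other called lists did. Of 56 Polycomb target regulators outside the Hox clusters 4 rose and 7 fell, and the list did not pass (adjusted p = 0.252, or 4.60e-06 without DMSO replicate 1 and 9.63e-05 without dTAG-13 replicate 2). Of 17 Hox genes Hoxb9 rose by 0.87 (list adjusted p = 0.18), and of 29 genes for Polycomb components 5 fell, with Phc1 at -0.51 (list adjusted p = 0.184). Without DMSO replicate 1 or dTAG-13 replicate 2 the pluripotency list turned in direction (0.94 and 0.909), and the ribosomal list did not pass (0.32 and 0.548), nor did the p53 list without dTAG-13 replicate 2 (0.243). Without dTAG-13 replicate 1 or DMSO replicate 2 the mesoderm, protocadherin and immediate early lists turned. As in the RNA set, fits without 1 library also drop the clone term, so clone baselines enter these list changes.

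In total 974 genes rose and 769 fell of 16496 tested, 116 and 74 by at least 2-fold. Without the clone term 0 passed, DESeq2 with the clone called 283 and 214, and leaving out any 1 of the 4 libraries together with the clone term left 0 in each case. Without DMSO replicate 2 (clone G9) the fold changes of T, Cyp26a1, Fgf8 and Eomes turned to 0.31, 0.35, 0.14 and 0.42.

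X-linked genes were compared with autosomal genes because the lines are female and the series names X inactivation. Xist, the RNA that coats the inactive X chromosome, stood at 931 ± 224 and 780 ± 349 CPM on days 4 to 7 (log2 -0.25, adjusted p = 0.63), at -0.21 on days 7 to 10 (adjusted p = 0.999) and at -0.14 in the RAD21 RNA set (adjusted p = 0.217). In PRO-seq it rose from 123 ± 6.03 to 156 ± 24.9 CPM (log2 0.33, adjusted p = 0.00269). Its antisense partner Tsix had log2 fold changes of 0.13, -0.10, 0.13 and 0.06 in the 4 comparisons and did not pass in any. The counting rule for strand is not given in the sources used here, so no stated rule separates the reads of this overlapping pair. Ftx, a non-coding gene of the X-inactivation centre, fell by 0.87 on days 4 to 7 and by 0.49 in the RAD21 RNA set.

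The median log2 fold change of 542 X-linked genes on days 4 to 7 was 0.142 against -0.013 for autosomal genes, and camera gave adjusted p = 0.0526 over the 4 comparisons, 0.0485 with the replicate block and 0.381 with an estimated correlation. It was 0.00444 without dTAG-13 replicate 1 and 0.0466 without DMSO replicate 2. The X chromosome held 3.49 ± 0.026% of counts with DMSO and 3.77 ± 0.207% with dTAG-13 (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest this design allows, with pairs ignored), and the share rose in each pair, from 3.50 to 3.55% and 3.47 to 3.81% in clone H7 and 3.52 to 3.96% in clone H2. The ratio of X-linked to autosomal median CPM was 0.904 ± 0.005 and 0.984 ± 0.083 (exact permutation p = 0.4), and in the pair of replicate 1 it fell from 0.9 to 0.892. On days 7 to 10 both medians were -0.013 (adjusted p = 0.587). In the RAD21 RNA set 527 X-linked genes had a median of -0.058 against 0.008 (adjusted p = 0.00887, and adjusted p = 0.336 with an estimated correlation), which became 0.0526 without the clone term, 0.639 without DMSO replicate 1 and 0.725 without dTAG-13 replicate 2. In PRO-seq the medians were 0.038 and -0.004 (adjusted p = 0.251).

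**Figure D2:**
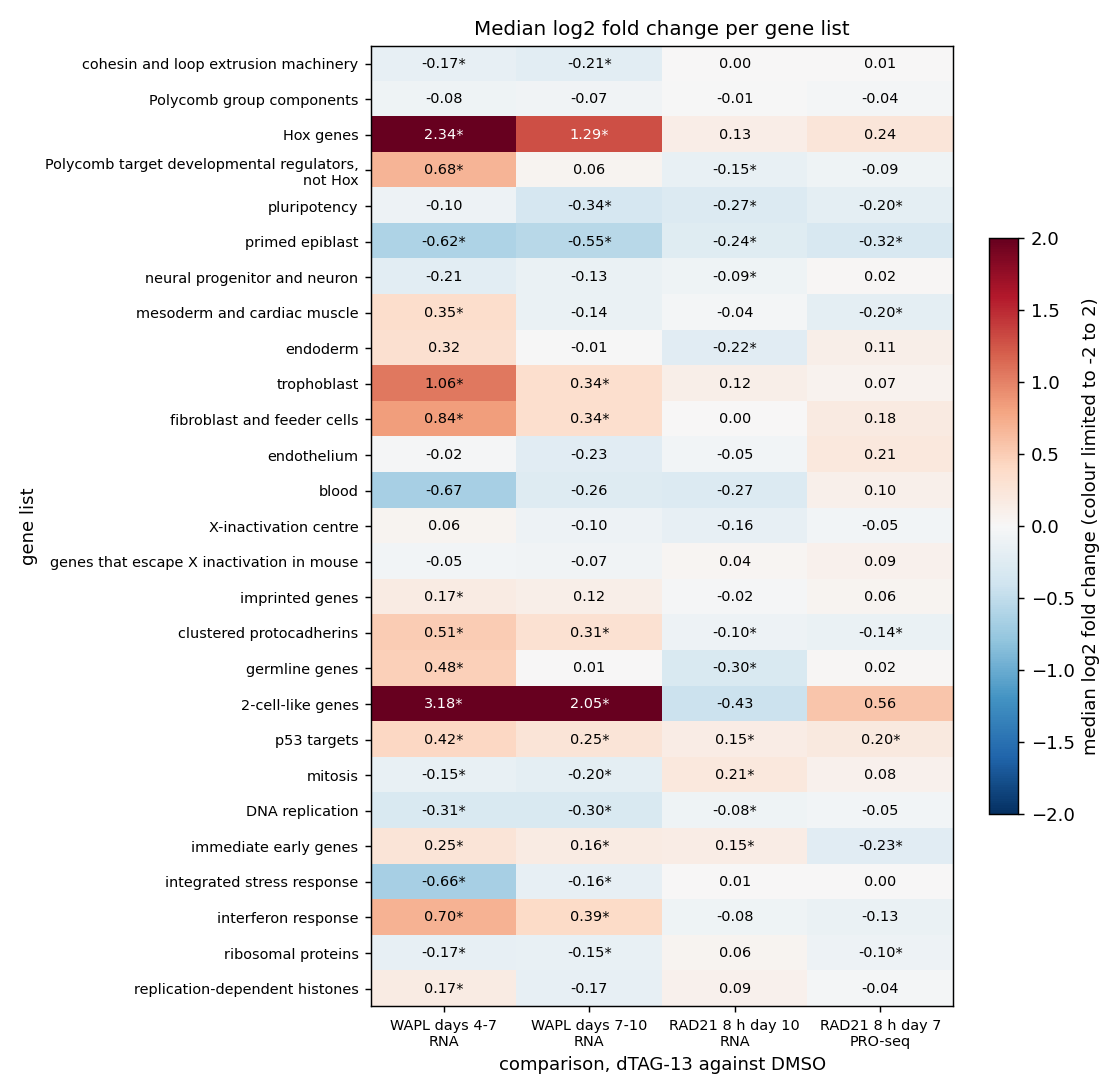
Median log2 fold change of dTAG-13 over DMSO for each gene list (vertical axis) in the 4 comparisons (horizontal axis), with red above 0 and blue below; an asterisk marks lists past adjusted p 0.05 in camera with a preset correlation of 0.01, none of which passed with an estimated correlation. The 2-cell-like list had a median of 3.18 on days 4 to 7 and the Hox list 2.34.

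Responses were then compared between comparisons, which share no control libraries. RAD21 RNA and PRO-seq fold changes correlated across 13324 genes with Pearson r = 0.38 and Spearman rho = 0.32, and of 675 genes called in both 616 (91.3%) had the same sign. They shared 304 rises against 77.9 from independent lists (Fisher's exact test, adjusted p = 2.55e-111) and 312 falls against 65.4 (adjusted p = 1.38e-142). Genes are not independent replicates and clones C4 and G9 stand behind both sets, so these p-values do not measure replication. WAPL days 4 to 7 and RAD21 PRO-seq correlated with r = 0.39 and rho = 0.35, with 454 of 497 shared calls (91.3%) of the same sign. WAPL days 4 to 7 and RAD21 RNA correlated with r = 0.20 and rho = 0.19, with 583 of 735 (79.3%) of the same sign. Of 12993 genes tested in the 3 comparisons with calls, 145 rose in all of them, including Acta2, Mdm2, Cdkn1a and Cdkn1c, and 93 fell in all of them, including Magel2, Sox2, Fgf5, Dnmt3b, Sall1, Eomes, Spon1 and Adamts15. These examples were picked after their values were seen.

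**Figure D3:**
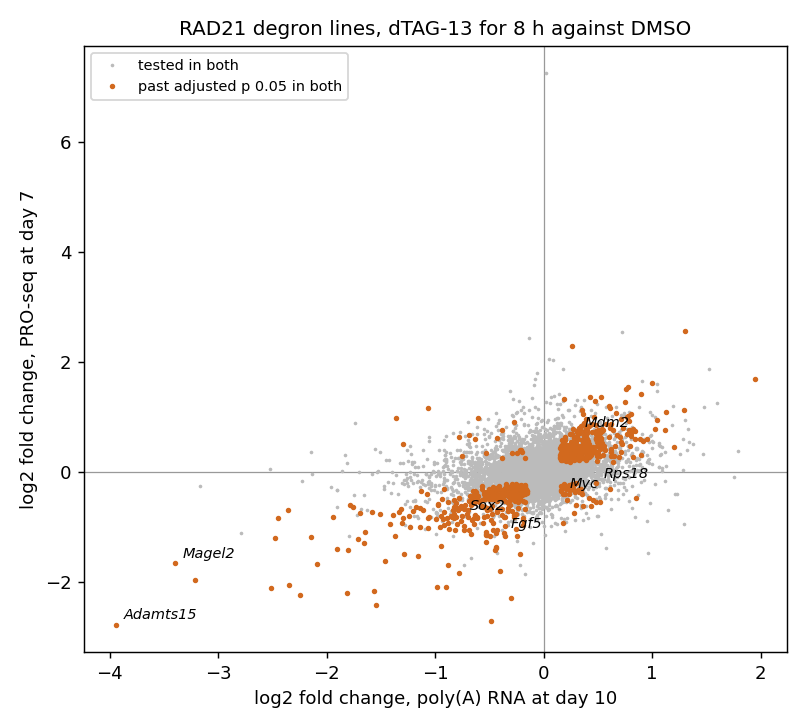
Log2 fold change of dTAG-13 over DMSO after 8 h in the RAD21 degron lines, poly(A) RNA at day 10 (horizontal) against PRO-seq at day 7 (vertical), 1 point per gene tested in both; orange points passed adjusted p 0.05 in both. Of 675 such genes 616 had the same sign, and Myc and Rps18 lay on opposite sides of 0.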

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

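The patterns and tests in this part were chosen after the data were seen, except the test of a stage shift and the count of splits, whose rules were written before their results. For the stage shift, the requirement that a second gene set also meet the bounds was added after the result was seen.

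Rps18 and Myc moved in opposite directions after 8 h of dTAG-13 in both RAD21 clones: Rps18 rose by 0.49 in RNA at day 10 (adjusted p under 0.05) and fell by 0.20 in PRO-seq at day 7 (adjusted p = 0.0466), and Myc rose by 0.18 (adjusted p = 0.0168) and fell by 0.40 (adjusted p = 0.0115). The difference itself was not tested, and assay and day differ between the pair. Rps18 has near-identical copies, so its counts are uncertain. Without DMSO replicate 2 and the clone term the PRO-seq value of Myc was 0.18.

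The rise of 2-cell-like genes on days 4 to 7 was weighed first. Reads shared between copies are argued against as the whole cause only by Tmem92 and Zfp352, members outside the multi-copy families. Their median log2 fold change was 2.57, above a bound of 1 that was set after the data were seen. Both are among the called members that made up the pattern, so this is no separate test. The list median rose in each of the 3 pairs, by 2.62, 3.13 and 3.85, so the rise was not confined to 1 pair. The pattern was picked from these same pairs, so their medians are no separate check. An effect of dTAG-13 itself stays open: the list median was -0.43 over 5 members in RAD21 RNA, where exposure was 8 h and not 3 days, and no line without a degron given dTAG-13 was analysed here. With that open, WAPL loss may account for the rise only as a hypothesis.

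A stretch of chromosome 14 stood apart in clone H7. Over 58 genes from Hesx1 to the neighbour of Wapl the DMSO libraries of clone H7 stood 2.81-fold over clone H2, while the 9 genes after Wapl had a median log2 ratio of -0.43. A tagged Wapl transcript alone is argued against only by how the stretch was defined, through high DMSO ratios of its other genes. Their median of 1.58 in the dTAG-13 libraries of the same clones adds no separate test. A low level in clone H2 is argued against by a median of 1.28 against the RAD21 lines (57 genes, separate tables). A difference in cell makeup would follow gene function and not position. It is argued against as the whole cause by position in the dTAG-13 libraries. There the highest median over 9 neighbouring genes was 1.69 on the stretch and 0.97 off it. Of 1000 shuffles of gene positions, 0 reached 1.69 anywhere (highest 1.11). In those libraries 46 of the 58 genes had a log2 ratio above 1. The same clones defined the stretch, so this count adds no separate test. Extra DNA copies may explain it (RNA fold 2.81) but stay untested, as no DNA library was analysed here, and 6 genes of the stretch were called for treatment.

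The third pattern was the 238 genes called the same way in WAPL days 4 to 7 and both RAD21 comparisons. A trend with expression level is argued against as the whole cause, since the correlation of WAPL and PRO-seq fold changes was 0.36 after it was taken out and 0.39 before. For a shared shift in differentiation stage, the genes changed from DMSO day 7 to day 10 in the direction of their response by a median of 0.47 (95% interval 0.4 to 0.58, 81.9% the same way), but those day 7 libraries are also controls of the WAPL response, which can push this value upward, and day is confounded with table. The 608 genes with same-sign calls in both RAD21 sets, picked without these libraries, gave 0.18 (0.14 to 0.23, 63.7%), short of the bounds of 0.25 and 70%. The shared libraries and the confounded day keep a stage shift open, so it cannot be told apart from other causes here. An effect of dTAG-13 on the 238 genes stays open too.

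For the 2209 genes of WAPL days 4 to 7, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many, the real one, and the highest of the others gave 0. The splits ignored the pairs of same-numbered libraries. With 10 splits a share under 0.05 cannot be had.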

How the results depend on the processing

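Fits of X-linked genes, gene lists and the difference between windows without 1 library, and 2 quasi-likelihood settings, were chosen after the data were seen. The count of WAPL days 4 to 7 (2209) kept within 1.5 times under both scalings, both filters, DESeq2 (2556), limma-voom (2121) and the added settings, and was 3993 with the replicate block, 994 without the clone term, 360 in clone H7 alone and 341 to 4433 without 1 library. WAPL days 7 to 10 gave 0, but 40 with DESeq2, 27 to 143 without 1 library and 5141 with the replicate block (r = 0.79 for each of 2 pairs, which share only a number). RAD21 RNA gave 2708, 475 with DESeq2, 1 with no replicate block (clone left out) and 16 to 94 without 1 library; PRO-seq gave 1743, 497, 0 and 0 to 0. The difference between windows went from 0 to 5 genes with the block. Fits without a library or clone term have fewer samples or let clone baselines in; the cause of the other changes was not tested. The block on days 4 to 7 changed the call of no list test but that of histones; called members per list were not counted with it. Allele shares had no alternative run, as no allelic counts were used here.

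X-linked genes on days 4 to 7 (adjusted p = 0.0526) passed at a mean count of at least 50 (0.0411) and with the block (0.0485) but not with an estimated correlation (0.381) or fry (0.0881), with 0.00444 to 0.251 without 1 library. In RAD21 RNA (0.00887) they did not pass with an estimated correlation (0.336) or no replicate block (0.0526), with 0.00119 to 0.725 without 1 library, and in PRO-seq (0.251) fry, which tests for any change and not against other genes, gave 0.0336. Lists past the threshold went from 19, 15, 11 and 7 to 0 in each comparison with an estimated correlation and to 11, 0, 0 and 0 with fry, and in PRO-seq to between 6 and 11 without 1 library. Calls that failed with an estimated correlation rest on the preset one. The tests with an estimated correlation had few residual degrees of freedom, so X-linked genes and lists stay undecided. At a mean count of at least 50 the correlation of the WAPL windows went from 0.77 to 0.80 and of RAD21 RNA and PRO-seq from 0.38 to 0.44.

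Directions turned only without 1 library, counted where either fit made a call. The ranges that follow cover only the fits without 1 library and leave out the main fit. In the main fit camera gave adjusted p = 0.00707 for ribosomal proteins on days 7 to 10. It gave 0.931 for trophoblast genes in PRO-seq, which did not pass. Adjusted p ranged, on days 7 to 10, from 4.80e-23 to 8.78e-04 for ribosomal proteins and 0.00314 to 0.988 for histones; in RAD21 RNA from 2.82e-24 to 0.848 for pluripotency, 1.72e-09 to 0.88 for endoderm, 9.51e-07 to 0.471 for germline and 3.09e-11 to 0.608 for ribosomal proteins; in PRO-seq from 1.52e-10 to 0.94 for pluripotency, 1.04e-04 to 0.879 for mesoderm, 9.51e-04 to 0.0274 for trophoblast, 7.36e-13 to 0.289 for protocadherins and 1.07e-11 to 0.733 for immediate early genes. Fold changes in RAD21 RNA ranged from -0.41 to 0.02 (Esco2), -0.03 to 0.53 (Lef1), -0.90 to 0.11 (Sox17), -0.89 to 0.26 (Cer1), -0.04 to 0.64 (Krt7), -1.06 to 0.12 (Tex19.1) and -0.50 to 0.06 (Slc7a3). In PRO-seq they ranged from -5.11 to 0.35 (Cyp26a1), -3.96 to 0.31 (T), -2.29 to 0.14 (Fgf8), -3.09 to 1.02 (Lhx1), -0.53 to 0.03 (Sox11), -2.12 to 0.42 (Eomes), -2.87 to 0.24 (Foxa2), -2.89 to 1.85 (Gata6), -0.46 to 1.18 (Peg10), -0.07 to 0.68 (Shroom4), -1.43 to 2.59 (Tuba3b), -0.88 to 0.06 (Nr4a1), -1.10 to 0.15 (Vldlr), -0.72 to 0.07 (Hist1h2bh) and -0.88 to 0.18 (Myc).

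Of 100 named genes called on days 4 to 7, 98 or more kept their call under scaling, no filter, DESeq2, limma-voom, the added settings and the block, 89 at a mean count of at least 50 (91 had a value), 77 without the clone term, 51 in clone H7 alone and 51 to 99 without 1 library. Under scaling, both filters, limma-voom and the added settings 93 or more of 104 kept it in RAD21 RNA and 81 or more of 90 in PRO-seq. With DESeq2 50 (2 had no value) and 47 kept it, with no replicate block 1 and 0, and without 1 library 6 to 19 and 0. The shallowest library (8413212 counts) sets a floor of 0.357 CPM for 3 counts.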

Other observations

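The tests in this part were chosen after the data were seen.

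Immediate early genes differed between the RAD21 sets in the count of called members, 11 higher and 3 lower of 23 in RNA at day 10 and 1 higher and 12 lower of 22 in PRO-seq at day 7, with log2 fold changes of 0.97 and 0.16 for Atf3 and -0.16 and -0.58 for Egr1 in RNA and PRO-seq. The difference was not tested, and the PRO-seq list turned in direction without dTAG-13 replicate 1 (adjusted p = 0.733) or DMSO replicate 2 (0.373). Adding a clone-by-treatment term for WAPL days 4 to 7 found no gene whose response differed between clones H7 and H2 with edgeR (0 of 14544, 302 at an unadjusted p under 0.05). Clone H2 had 1 library per treatment and the spread came from clone H7 alone, so this does not show that the clones agree.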
